A study of Mus musculus with 11 samples.

How the data were processed

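RNA was measured by RNA-seq in whole-tissue cells of spleen and lymph node (LN) from 6 mice: 2 wild-type mice (Wt, mice 1 and 2), 2 mice carrying a BCL2 transgene under the 3' regulatory region of the immunoglobulin heavy chain locus (Tg, mice 3 and 4) and 2 mice with BCL2 knocked in at the kappa light chain locus (KI, mice 5 and 6). Per the labels, mice were immunised with sheep red blood cells 3 times over 3 months, tissue was taken 1 month after the last immunisation, and RNA came from dissociated cells with libraries made by a SMARTER kit. Mouse 3 was used here for LN only, so 11 libraries formed 6 groups of tissue and genotype, each of 2 libraries except spleen Tg with 1. Sample numbers in the labels pair the spleen and LN of 1 mouse.

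The submitters' processing notes list FastQC 0.11.5, STAR 2.5, featureCounts (no version), Subread 1.4.6, DESeq2 1.26.0 and the build GRCm39, with no role or order. Annotation release, strand setting and gene filter were not given in the sources used here. The deposited table holds a normalised signal for 10885 genes per library, made by the authors by dividing gene read counts by 1 factor per library, as DESeq2's size factors do; the division was read from the values, not from a statement. Each gene reached at least 109.3 in at least 1 library, so weakly expressed genes could not be examined. In all 11 libraries 100% of the values were whole multiples of 1 step per library, within a tolerance of 0.05 reads, and reads were taken as multiples of that step. A further check on low values alone needed 100 of them, which the 6 LN libraries held and the 5 spleen libraries did not, so count-based tests were run on LN only. Gene symbols came from the deposited table. GENCODE M21, which matched 10875 of the 10885 identifiers, gave chromosomes and the order of neighbouring genes by start position. It is of another build, so no positions are reported from it.

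LN depth, as recovered reads over the genes of the table, was 11128568 (Wt mouse 1), 16483630 (Wt mouse 2), 12165371 (Tg mouse 3), 21067988 (Tg mouse 4), 16442383 (KI mouse 5) and 15125180 (KI mouse 6). The normalised values of a library summed to between 17217404 and 18046250 over all 11 libraries. By the same step, spleen depth was 18994455 (Wt mouse 1), 22471896 (Wt mouse 2), 22310498 (Tg mouse 4), 20476366 (KI mouse 5) and 24110325 (KI mouse 6) reads.

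The comparisons and their tests, 30 gene lists of pathways and cell type markers, and the rule for naming genes were chosen before the data were examined. An edgeR quasi-likelihood test had been planned for counts; since the table holds normalised values, the planned substitute was used, limma-trend 3.58.1 (R 4.3.3) on log2(value + 1), with empirical Bayes moderation (trend and robust) and no further filter. Group means of the 6 groups were fitted over all 11 libraries, which left 5 residual degrees of freedom. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. Tg was compared with Wt, KI with Wt and KI with Tg in each tissue; the Tg and KI effects were compared between tissues as interactions; and LN was compared with spleen with genotype and tissue as additive terms. The lone Tg spleen library was assumed to vary like the other groups. The mouse was not a term of these fits. As alternatives it was fitted as a random term (duplicateCorrelation, statmod 1.5.0, consensus correlation 0.0168) and, for interactions and tissue, as a fixed term. At that consensus the random term could change little. Yet deviations from the group mean correlated over genes between the 2 tissues of 1 mouse, at 0.403 in Wt and 0.900 in KI. Errors beside log2 fold changes are standard errors of the fit; errors beside normalised values are SDs over 2 mice.

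Of the 30 lists, 27 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, with p adjusted over the lists of a comparison. Fry asks whether a list's genes moved one way on balance and does not compare the list with other genes. The 3 lists not tested held 0 genes of lymphoid stroma, 0 of exocrine pancreas and 2 of adipocytes. In each comparison, named genes were Bcl2; up to 10 called genes with the largest increase and 10 with the largest decrease, among those with a mean log2 CPM of at least 2 and no overlap between the groups' libraries; and up to 4 called members with the smallest p of each list, or up to 2 uncalled members where none was called. Where no gene was called, the 5 with the smallest p were named, as were the 5 with the smallest p in each interaction. Immunoglobulin and T cell receptor segments, pseudogenes and predicted genes were summarised as classes. Sex was checked from Xist and 4 Y-linked genes in each library.

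Alternatives tried were pseudocounts of 0.1 and 5, removal of immunoglobulin and haemoglobin genes, fits to 1 tissue or 2 groups only, and the omission of each library in turn. Chosen after seeing the data were scaling to total counts, quantile normalisation, a limma treat test against a 1.5-fold change, a minimum value of 100 in at least 2 libraries, the omission of mouse 1, 5 or 6, and edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered LN reads. The tests were also run on simulated data with 200 changed genes, 67 of them changed 2-fold. Of these 67, limma-trend recovered 73.1% for LN Tg against Wt, 67.2% for LN KI against Wt and 67.2% for spleen KI against Wt. It recovered 47.8% for spleen Tg against Wt and 23.9% for the KI interaction. In the simulation of LN KI against Wt, 7 of 130 limma-trend calls were wrong, as were 5 of 104 edgeR calls and 66 of 203 DESeq2 calls. The simulated libraries were independent and had 1 spread per gene in all groups. In the data KI replicates differed more than the others, and the 2 tissues of 1 mouse deviated together. The simulated rates may therefore not hold for the KI comparisons and the interaction. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.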

Results

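Gene expression was compared in the spleen and LN of immunised Wt mice and of mice carrying BCL2 in either of 2 B cell settings, the 3' regulatory region of the heavy chain locus (Tg) or the kappa light chain locus (KI). There were 11 libraries: 2 each for spleen Wt, LN Wt, LN Tg, spleen KI and LN KI, and 1 for spleen Tg. Recovered LN depth lay between 11128568 and 21067988 reads. Replicates of Wt and Tg lay closer to each other than those of KI: the SD of the log2 difference between replicates was 0.451 in spleen Wt, 0.493 in LN Wt, 0.449 in LN Tg, 0.903 in spleen KI and 0.918 in LN KI. Mouse 1 (Wt) was female by Xist, with a normalised signal of 14513 in spleen, and the other 5 mice were male by Ddx3y, between 1452 and 3064. Immunoglobulin genes took 1.90% and 2.18% of the signal in the Wt spleens, 8.23% and 5.25% in the KI spleens, 0.662% and 0.751% in Wt LN, and 9.46% and 6.77% in KI LN.

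Bcl2 (ENSMUSG00000057329), the anti-apoptotic gene that both models carry as an insertion, was first read in each library. Its normalised signal was 2519 ± 131 (SD, n = 2) in spleen Wt, 1274 ± 35.6 (SD, n = 2) in spleen KI and 2109 in the 1 spleen Tg library. In LN it was 2527 ± 267 (SD, n = 2) in Wt, 2618 ± 782 (SD, n = 2) in Tg and 1455 ± 296 (SD, n = 2) in KI. Bcl2 fell by 0.98 ± 0.20 on the log2 scale in KI spleen against Wt (limma adjusted p = 0.011) and by 0.81 ± 0.20 in KI LN (limma adjusted p = 0.0152), with both KI libraries below both Wt libraries in each tissue. Tg minus Wt was 0.02 ± 0.20 in LN and -0.26 ± 0.24 in spleen, neither called (limma adjusted p = 0.999 in LN). These values count reads assigned to the mouse gene; the species and form of the inserted BCL2 were not stated in the sources used here, so its own transcript may be counted in part or not at all. The spleen call was lost without any 1 of the 4 Wt or KI spleen libraries, where the difference ranged from -1.04 to -0.93, and the LN call was lost without Wt mouse 2 (-0.70) or KI mouse 5 (-0.60). In LN Tg minus Wt the sign turned without Tg mouse 4 (-0.29).

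**Figure D1:**
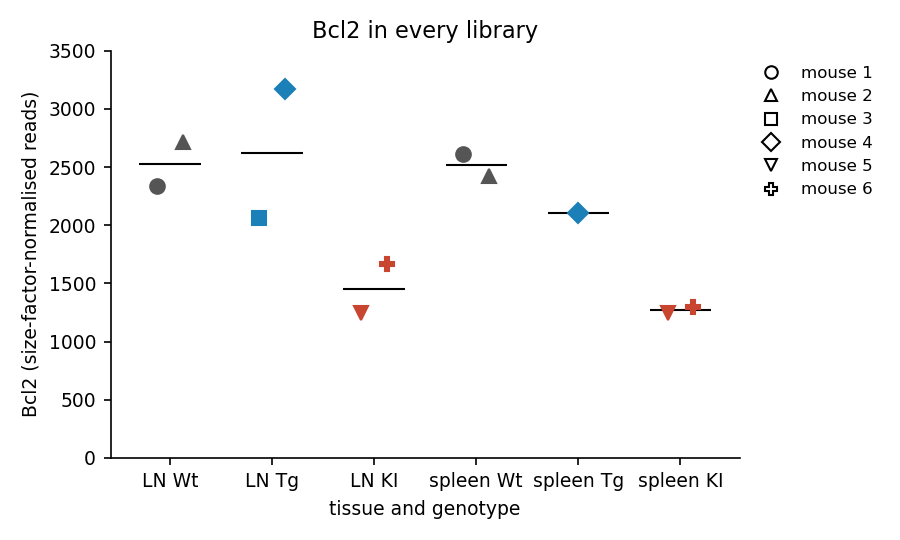
Normalised signal of Bcl2 (vertical axis, reads divided by the size factor) in each library, by tissue and genotype; points are libraries, marked by mouse, and horizontal lines are group means. The 4 KI libraries lie between 1246 and 1664, below the 4 Wt libraries, which lie between 2338 and 2716.

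Against Wt, the Tg mice tested the effect of BCL2 under the heavy chain regulatory region. In LN no gene was called: limma gave 0 at an adjusted p under 0.05 and 532 at an unadjusted p under 0.05, against 544 by chance, while edgeR and limma-voom gave 0 and DESeq2 gave 29 (28 higher and 1 lower). In 50 simulations of unchanged LN groups, chosen after seeing the data, DESeq2 called 13 to 32 genes higher in Tg and 13 to 33 lower. The observed 1 lower gene lay below that range. These simulations gave Wt and Tg a spread pooled over all groups. The SD of the log2 difference between replicates was 0.918 in LN KI, but 0.493 in LN Wt and 0.449 in LN Tg. They may therefore overstate false calls in Tg against Wt and cannot judge the 28 genes. The 5 genes with the smallest p were all higher in Tg LN: Scn8a (sodium channel) by 2.29 ± 0.32, Pdzd2 by 1.71 ± 0.24, Ret (receptor tyrosine kinase) by 2.38 ± 0.35, Hpse (heparanase) by 1.25 ± 0.19 and Sema7a (semaphorin) by 0.97 ± 0.15 on the log2 scale, each with limma adjusted p = 0.103 and n = 2 against 2. None of the 18 germinal centre genes was called over all genes and 4 rose when adjusted over the list alone; their median was 0.70, with Rgs13 (a regulator of G protein signalling in germinal centre B cells) at 1.81 ± 0.35 and Neil1 (DNA glycosylase) at 0.94 ± 0.15. As a list they were higher than other genes by camera (adjusted p = 4.37e-14), which was lost at adjusted p = 0.275 with an estimated correlation. Pdzd2, Ret, Hpse, Rgs13, Scn8a, Sema7a and Neil1 were also among the 28 genes higher by DESeq2. Macrophage genes had a median of 0.46, including Cd5l at 0.88 ± 0.28 and Axl at 0.56 ± 0.18. Camera gave macrophage genes adjusted p = 5.28e-08, and adjusted p = 0.275 with an estimated correlation. The plasma cell list had a median of 0.25, with Jchain (which joins immunoglobulin polymers) at 0.71 ± 0.26. The plasma cell list had camera adjusted p = 8.84e-05, and adjusted p = 0.315 with an estimated correlation. In the pan T cell list the median was -0.16, with Cd3e at -0.34 ± 0.12. Camera gave pan T cell genes adjusted p = 0.000377, and adjusted p = 0.454 with an estimated correlation. Of 27 lists 16 were called by camera, 0 with an estimated correlation and 0 by fry. Without Wt mouse 2 limma called 9 genes, and without Tg mouse 3 it called 13; in LN Tg minus Wt the 1 gene lower by DESeq2 was Xist, by which mouse 1 differs in sex.

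In spleen the same question rested on 1 Tg library against 2 Wt libraries. No gene was called by limma, against 164 at an unadjusted p under 0.05 with 544 given by chance, and no count-based tool was run on spleen. The 5 genes with the smallest p were Prg2 (an eosinophil granule protein) at 1.99 ± 0.41, Sema7a at 0.84 ± 0.18, Scart2 at -1.73 ± 0.38, Tgfa (an epidermal growth factor receptor ligand) at 2.66 ± 0.64 and Acacb (acetyl-CoA carboxylase) at -1.51 ± 0.42. The germinal centre list had 0 called members and a median of 0.75, with Efnb1 (ephrin B1) at 1.21 ± 0.34 and Rgs13 at 1.29 ± 0.42. The germinal centre list had camera adjusted p = 1.18e-07, and adjusted p = 0.605 with an estimated correlation. For neutrophil genes the median was 1.45 with 0 called. Camera gave neutrophil genes adjusted p = 0.000246, and adjusted p = 0.763 with an estimated correlation. Of the lists 7 were called by camera, and 0 by fry or with an estimated correlation. On simulated data 47.8% of 2-fold changes were recovered at these group sizes. The error of the fit was pooled over all groups. KI replicates differed more than Wt replicates, with an SD of the log2 difference of 0.903 in KI spleen and 0.451 in Wt spleen. The pooled error may therefore be too large for Tg against Wt. The absence of calls does not show that Tg had no effect in spleen.

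Most plasma cell genes and many antibody genes were higher in KI LN than in Wt LN, but 0 of 79 kappa V segments were called. Jchain was 5.24 ± 0.26 higher on the log2 scale (limma adjusted p = 1.28e-05; normalised signal 125722 ± 4346 in KI and 3336 ± 515 in Wt, SD, n = 2 each), and the heavy chain constant regions Ighg2c and Ighg2b were 5.94 ± 0.62 and 5.37 ± 0.63 higher. Of the 20 plasma cell genes 17 rose and 0 fell (17 and 1 when adjusted over the list alone), including Sdc1 (the plasma cell surface protein CD138) by 4.17 ± 0.18, Derl3 (endoplasmic reticulum degradation) by 3.94 ± 0.20 and Mzb1 (an immunoglobulin chaperone) by 2.93 ± 0.14; the list was called by camera (adjusted p = 2.06e-13, and adjusted p = 0.143 with an estimated correlation). Germinal centre genes rose as well, 13 of 18 with 0 that fell (14 and 1 adjusted over the list alone), among them Rgs13 by 3.97 ± 0.35, Mybl1 (a transcription factor of germinal centre B cells) by 4.47 ± 0.57, Efnb1 by 3.02 ± 0.28 and Neil1 by 2.30 ± 0.15. The germinal centre list had camera adjusted p = 2.86e-08, and adjusted p = 0.226 with an estimated correlation. Of 12 immunoglobulin constant regions 7 rose and 1 fell (9 and 1 adjusted over the list alone), with Igha at 2.80 ± 0.28 and Ighm at 1.17 ± 0.16. Camera gave constant region genes adjusted p = 9.79e-06, and adjusted p = 0.112 with an estimated correlation. Any reads shared between similar constant regions, such as Ighg2b and Ighg2c or the lambda constant regions, leave the split between such genes uncertain.

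Interferon response genes rose in KI LN, 17 of 18 with 0 that fell (17 and 0 adjusted over the list alone), including Oas1a by 2.65 ± 0.24, Irf7 (an interferon-inducing transcription factor) by 2.59 ± 0.25 and Stat2 by 1.08 ± 0.11. The interferon list had camera adjusted p = 8.05e-12, and adjusted p = 0.181 with an estimated correlation. Proliferation genes rose in 21 of 27 cases with 0 that fell (21 and 0 adjusted over the list alone), such as the mitotic kinases Bub1b by 1.46 ± 0.25 and Aurkb by 1.36 ± 0.27. Camera gave proliferation genes adjusted p = 2.03e-07, and adjusted p = 0.554 with an estimated correlation. In the unfolded protein response list 11 of 15 rose and 0 fell (11 and 2 adjusted over the list alone), with the chaperones Hsp90b1 at 1.60 ± 0.17 and Sdf2l1 at 1.72 ± 0.20. The unfolded protein response list had camera adjusted p = 4.77e-05, and adjusted p = 0.181 with an estimated correlation. Outside the lists, Thbd (thrombomodulin) rose by 5.56 ± 0.52, Cacna1h (a calcium channel) by 4.95 ± 0.30 and Reln (reelin, a secreted matrix protein) by 4.82 ± 0.30. B cell receptor signalling genes rose in 11 of 20 cases and fell in 2 (12 and 2 adjusted over the list alone), with Fcgr2b, an inhibitory Fc receptor, at 1.16 ± 0.10. Camera gave B cell receptor genes adjusted p = 0.00172, and adjusted p = 0.656 with an estimated correlation. Pan B cell genes rose in 9 of 20 and fell in 2 (9 and 2 adjusted over the list alone), with Pou2af1 at 1.14 ± 0.14 and Fcer2a at -1.22 ± 0.17. The pan B cell list had camera adjusted p = 0.00264, and adjusted p = 0.706 with an estimated correlation.

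T cell genes fell in KI LN: 17 of 20 pan T cell genes fell and 0 rose (19 and 0 adjusted over the list alone), with Lef1 at -1.51 ± 0.15, Cd6 at -1.16 ± 0.11 and Tcf7 at -1.15 ± 0.12. Camera gave pan T cell genes adjusted p = 3.65e-12, and adjusted p = 0.181 with an estimated correlation. Macrophage genes fell in 9 of 17 cases with 0 that rose (9 and 0 adjusted over the list alone), with Slc40a1 (the iron exporter ferroportin) at -2.91 ± 0.30 and the complement genes C1qa and C1qc at -1.74 ± 0.23 and -1.76 ± 0.22. The macrophage list had camera adjusted p = 2.35e-05, and adjusted p = 0.181 with an estimated correlation. Of 16 NF-kB targets 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them Tnfaip3 (the NF-kB inhibitor A20) at -3.27 ± 0.53 and Ccl22 (a chemokine) at -2.87 ± 0.39. Camera gave NF-kB genes adjusted p = 0.000202, and adjusted p = 0.181 with an estimated correlation. Further large decreases were Atf3 (a stress transcription factor) at -3.57 ± 0.51, Tspan9 at -2.93 ± 0.39, Pdlim4 at -2.69 ± 0.23, Fcna at -2.69 ± 0.49 and Plk2 at -2.65 ± 0.32. Immediate early and marginal zone lists were not called (camera adjusted p = 0.0556 and 0.0598), but were without mouse 1 (adjusted p = 0.0154 and 0.0182), the former also without mouse 5 (0.00656).

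In all, limma called 2833 genes in KI LN against Wt, 1502 higher and 1331 lower, of which 1085 differed over 2-fold. At an unadjusted p under 0.05 limma gave 4115 genes, against 544 by chance. With immunoglobulin and haemoglobin genes left out, the median of all genes shifted by 0.131 on the log2 scale and the split became 2066 higher and 879 lower, and after quantile normalisation it turned to 1237 higher and 1420 lower, while no called list's median changed sign under any scaling, taken as it stands or relative to all genes. The count was 1833 without Wt mouse 2, 1465 without the LN of KI mouse 5, and 1695, 1318 and 1772 without both tissues of mouse 1, 5 or 6. Of the 54 named called genes besides Bcl2, 8 lost their call when a library or mouse was left out, at adjusted p between 0.0501 and 0.144: Iglc1, Ifit3, Slpi, Apol8, Dusp5, Tnfaip3, Ccr7 and Cr2. Apol8 and Dusp5 without KI mouse 5 or 6 ranged from -3.39 to -2.51 and from -2.68 to -2.58, Ifit3 from 4.20 to 4.82, and Slpi, also without Wt mouse 2, from 4.05 to 4.51. Iglc1 ranged from 4.98 to 6.42 without Wt mouse 1, Wt mouse 2 or KI mouse 6, Cr2 from -0.65 to -0.52 without Wt mouse 2 or KI mouse 6, Tnfaip3 from -3.51 to -3.04 without KI mouse 5 or 6, and Ccr7 was -1.93 without KI mouse 5. Among the lists named above, the camera call of pan B cell genes was lost without mouse 5 (adjusted p = 0.058; 0.0465 without mouse 1 and 7.7e-05 without mouse 6), at medians of 0.20 to 0.57, and the other list calls were kept. Without mouse 1, 5 or 6, in that order, members that rose numbered 6, 6 and 8 of pan B cell genes, 11, 6 and 15 of proliferation genes, 7, 6 and 11 of B cell receptor genes, and 7, 10 and 7 of the unfolded protein response, while NF-kB targets that fell numbered 8, 4 and 4. Camera called 11 of the 27 lists and fry 12. Genotype is not separable from breeding colony or handling day, which the labels do not give.

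**Figure D2:**
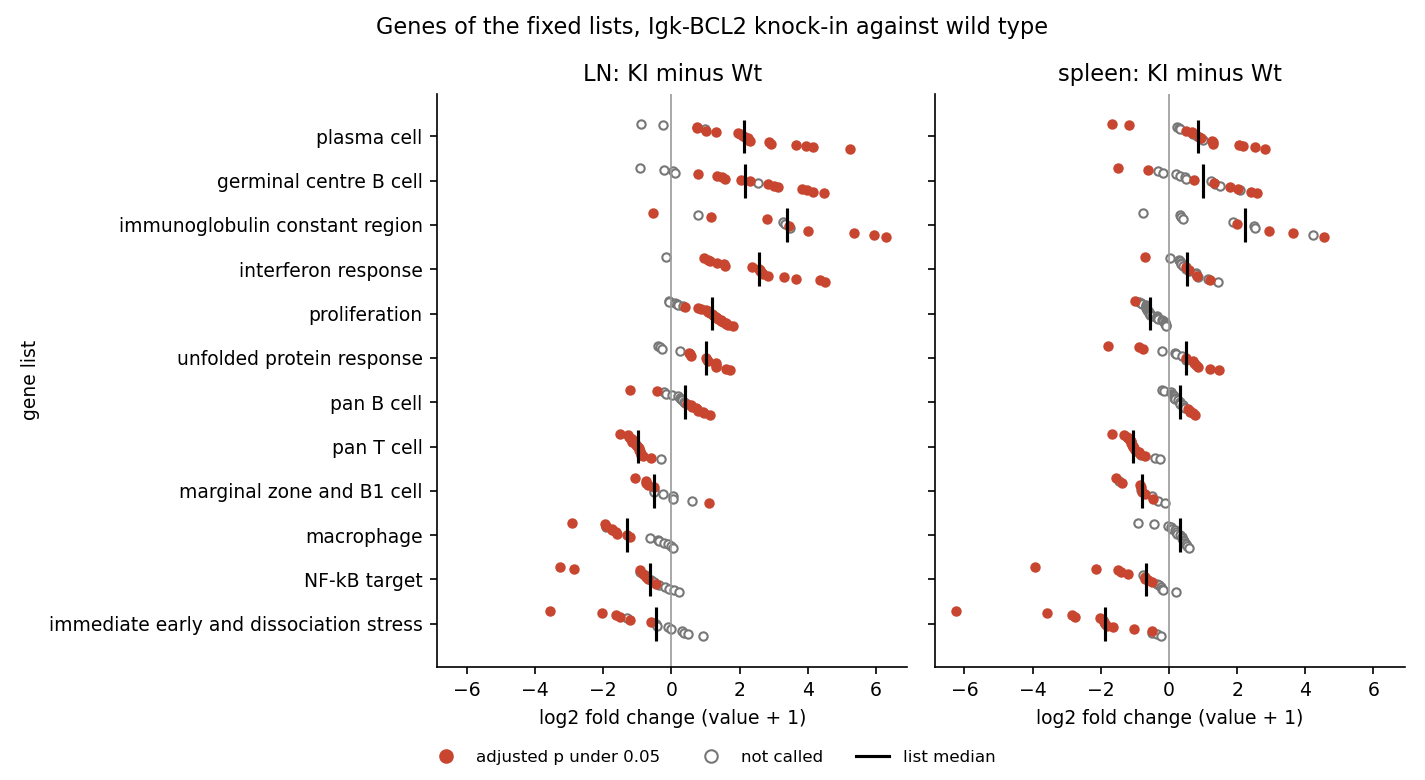
Log2 fold change of KI minus Wt (horizontal axis) of the measured genes of 12 fixed lists (vertical axis), in LN and spleen; points are genes, filled where called, and vertical lines are list medians. Plasma cell genes have medians of 2.12 in LN and 0.86 in spleen, pan T cell genes -0.99 and -1.05.

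In KI spleen, most plasma cell genes and some antibody genes rose, and T cell and immediate early genes fell. Of the 20 plasma cell genes 12 rose and 2 fell (14 and 2 adjusted over the list alone; those that fell were Cd28 and Irf4), with Jchain at 2.81 ± 0.26, Sdc1 at 2.53 ± 0.18 and Derl3 at 2.19 ± 0.20. The plasma cell list had camera adjusted p = 2.66e-07, and adjusted p = 0.197 with an estimated correlation. The stress transcription factor Atf3 was 3105 ± 1007 in Wt spleen and 38.9 ± 1.69 in KI spleen (SD, n = 2 each), a log2 difference of -6.24 ± 0.51 (limma adjusted p = 0.000889). Of the 15 immediate early genes 10 fell and 0 rose (10 and 0 adjusted over the list alone), including Nr4a1 (a nuclear receptor induced by antigen receptor signals) at -3.59 ± 0.35 and Ier3 at -2.85 ± 0.37. Camera gave immediate early genes adjusted p = 2.36e-07, and adjusted p = 0.295 with an estimated correlation. Rgs1 at -3.89 ± 0.21, Plk2 at -4.14 ± 0.32, Gla (alpha-galactosidase) at -4.12 ± 0.26 and Dusp5 (a phosphatase of ERK) at -4.08 ± 0.48 fell with them. Pan T cell genes fell in 16 of 20 cases with 0 that rose (19 and 0 adjusted over the list alone), with Tcf7 at -1.23 ± 0.12 and Bcl11b at -1.31 ± 0.13. The pan T cell list had camera adjusted p = 2.02e-14, and adjusted p = 0.161 with an estimated correlation.

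Marginal zone and B1 genes fell in 7 of 12 cases with 0 that rose (9 and 0 adjusted over the list alone), with Cr2 (complement receptor 2) at -1.39 ± 0.16 and Myof at -1.56 ± 0.17. Camera gave marginal zone and B1 genes adjusted p = 4.1e-06, and adjusted p = 0.0745 with an estimated correlation. NF-kB targets fell in 9 of 16 cases with 0 that rose (10 and 0 adjusted over the list alone), including Tnfaip3 at -3.93 ± 0.53, Nfkbiz at -2.13 ± 0.29 and Nfkb2 at -0.71 ± 0.12. The NF-kB list had camera adjusted p = 5.96e-06, and adjusted p = 0.161 with an estimated correlation. Germinal centre genes rose in 6 of 18 cases and fell in 2 (12 and 2 adjusted over the list alone), with Rgs13 at 2.02 ± 0.35 and Efnb1 at 1.80 ± 0.28 against Ung (uracil DNA glycosylase) at -0.61 ± 0.14. Camera gave germinal centre genes adjusted p = 0.00129, and adjusted p = 0.55 with an estimated correlation. Immunoglobulin constant regions rose in 4 of 12 cases with 0 that fell (7 and 0 adjusted over the list alone), with Ighg2c at 4.55 ± 0.62 and Igha at 1.98 ± 0.28. The constant region list had camera adjusted p = 3.22e-05, and adjusted p = 0.0745 with an estimated correlation. Erythroid genes had a median of 2.60, 4 of 16 rose and 1 fell (6 and 1 adjusted over the list alone), with Car2 (carbonic anhydrase) at 1.68 ± 0.31. Camera gave erythroid genes adjusted p = 0.000182, and adjusted p = 0.55 with an estimated correlation. Outside the lists, Reln rose by 3.92 ± 0.30, the sialyltransferase St6galnac2 by 3.49 ± 0.30, Col27a1 (a collagen) by 3.19 ± 0.31, and Asns (asparagine synthetase) by 2.87 ± 0.41. The growth regulator Myc fell by 2.17 ± 0.15 on the log2 scale.

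For KI spleen, limma called 1833 genes, 830 higher and 1003 lower, 658 over 2-fold; with immunoglobulin and haemoglobin genes left out the split turned to 1427 higher and 816 lower, and to 1073 and 1011 after quantile normalisation. The count was 624 without Wt mouse 1, 747 without Wt mouse 2, 634 without KI mouse 5 and 656 without KI mouse 6, and of the 51 named called genes besides Bcl2, 21 lost their call in at least 1 such omission of a library or mouse, at adjusted p up to 0.234. Fosl2 (-3.84 to -3.75), Irs2 (-4.37 to -3.99), Maff (-4.64 to -4.40), Ighe (2.70 to 3.15), Ung (-0.66 to -0.56), Gbp2 (-0.81 to -0.58) and Stat2 (0.44 to 0.53) lost it without any 1 of the 4 libraries. Without Wt mouse 1 or 2 Ighg2b ranged from 3.38 to 3.91, and Tnfaip3, without Wt mouse 1 or either KI mouse, from -3.94 to -3.64. Without KI mouse 5 Nr4a2 was -3.94, and without KI mouse 6 Car2 was 1.49. Every list named above kept its camera call without mouse 1, 5 or 6, at adjusted p up to 0.00811, with fewer called members in most. In that order, those that rose numbered 7, 8 and 10 of plasma cell genes, 2, 1 and 5 of germinal centre genes, 2, 5 and 6 of constant regions and 0, 1 and 4 of erythroid genes (medians 1.64 to 3.01), and those that fell 3, 3 and 5 of marginal zone and B1 genes, 6, 2 and 2 of NF-kB targets and 6, 6 and 5 of immediate early genes. Neutrophil genes had a median of -2.25 with 0 of 16 called (camera adjusted p = 0.00433, and 0.562 with an estimated correlation). Without mouse 1, 5 or 6 that median was -3.73 with 5 that fell, -1.41 (camera adjusted p = 0.105) and -2.98. Camera called 16 of the 27 lists and fry 6. Leaving out both tissues of a mouse ended the calls of Ighg2c (4.10 without mouse 5), Dusp5 (-4.16 to -3.99), Rgs13 (1.60 to 1.67), Nfkb2 (-0.63), Nfkbiz (-2.03) and Cd79b (0.58).

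Kappa and lambda light chains set the 2 KI mice apart. Igkc, the kappa constant region, read 336217 in spleen and 419339 in LN of KI mouse 5, against 5793 and 4235 in KI mouse 6, with 69156 and 81719 in the Wt spleens and 22589 and 26307 in Wt LN. The 79 Igkv segments summed to 172700 and 206681 in mouse 5 and to 142 and 168 in mouse 6, against 36311 and 43756 in the Wt spleens and 12025 and 13578 in Wt LN. Lambda constant regions made up 96.5% and 98.0% of light chain constant signal in mouse 6, 10.7% and 8.22% in mouse 5, 9.20% to 12.3% in Wt and 6.67% to 13.2% in Tg. By Igkc and Igkv signal the 2 KI mice lay on either side of the other genotypes, and the median log2 difference of KI minus Wt over the 79 Igkv segments was -0.83 in LN and -2.77 in spleen. In LN 71 of 88 Ighv segments rose, with a median of 3.67, as did 3 Iglv segments, while 11 of 15 Trbv segments fell. In spleen 22 Ighv segments rose, with a median of 1.56, and 12 Trbv segments fell. These are normalised signals of single libraries, and reads shared between similar segments limit the values of single V segments.

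**Figure D3:**
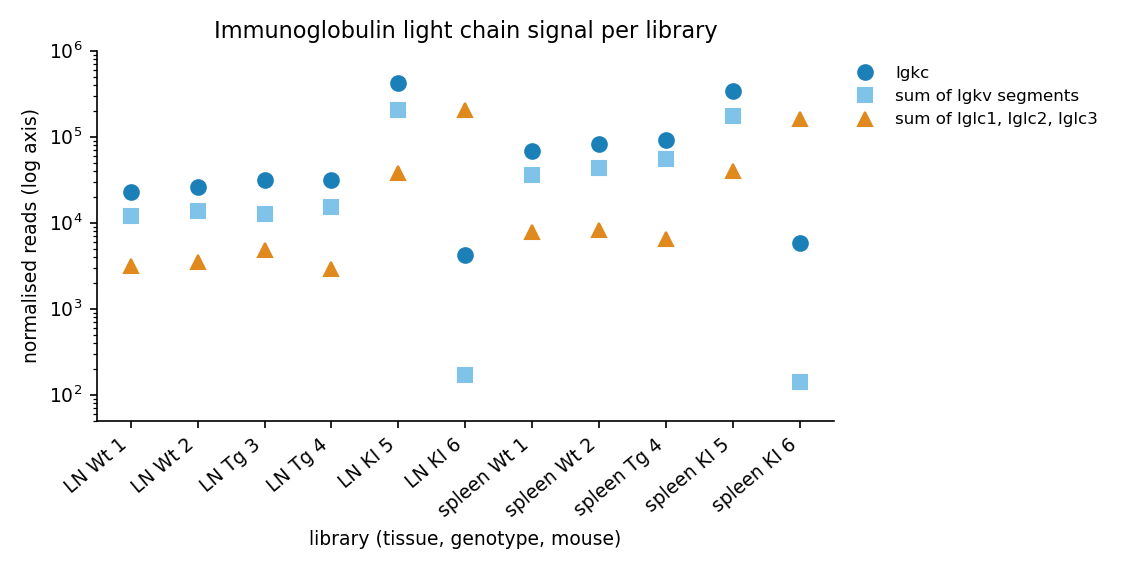
Light chain signal per library: kappa constant region, kappa V segments and lambda constant regions on a logarithmic axis of normalised signal. KI mouse 6 has Igkv sums of 142 in spleen and 168 in LN, against 172700 and 206681 in KI mouse 5.

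KI and Tg mice were compared directly in LN, with the same 2 KI libraries as against Wt. Plasma cell genes rose in 17 of 20 cases and fell in 1 (17 and 2 adjusted over the list alone), with Jchain at 4.53 ± 0.26, Sdc1 at 3.82 ± 0.18 and Mzb1 at 2.64 ± 0.14. The plasma cell list had camera adjusted p = 3.32e-11, and adjusted p = 0.14 with an estimated correlation. Germinal centre genes rose in 13 of 18 and fell in 1 (13 and 1 adjusted over the list alone), including Neil1 at 1.37 ± 0.15 and Bcl6 (the germinal centre transcription factor) at 1.08 ± 0.16. Camera gave germinal centre genes adjusted p = 9.48e-05, and adjusted p = 0.425 with an estimated correlation. Interferon genes rose in 17 of 18 with 0 that fell (17 and 0 adjusted over the list alone), with Ifit1 at 4.64 ± 0.58 and Rsad2 (viperin, an antiviral enzyme) at 3.91 ± 0.44. The interferon list had camera adjusted p = 2.68e-12, and adjusted p = 0.163 with an estimated correlation. Macrophage genes fell in 14 of 17 with 0 that rose (15 and 0 adjusted over the list alone), with C1qc at -2.32 ± 0.22 and Slc40a1 at -3.65 ± 0.30. Camera gave macrophage genes adjusted p = 6.08e-09, and adjusted p = 0.14 with an estimated correlation. In the pan T cell list 15 of 20 fell and 0 rose (17 and 0 adjusted over the list alone), with Cd6 at -1.10 ± 0.11 and Trac at -1.12 ± 0.13. The pan T cell list had camera adjusted p = 4.84e-10, and adjusted p = 0.163 with an estimated correlation. NF-kB targets fell in 10 of 16 with 0 that rose (12 and 0 adjusted over the list alone), with Ccl22 at -3.57 ± 0.39 and Relb at -0.98 ± 0.11. Camera gave NF-kB genes adjusted p = 1.88e-06, and adjusted p = 0.14 with an estimated correlation. Bcl2 itself fell by 0.83 ± 0.20 on the log2 scale (limma adjusted p = 0.0142), a call lost without Tg mouse 4 (-0.52) or KI mouse 5 (-0.62). Limma called 2910 genes, 1580 higher and 1330 lower (2046 and 1032 with immunoglobulin and haemoglobin genes left out, but 1288 and 1511 after quantile normalisation); 1830 were called from these 2 groups alone, 1341 without the LN of KI mouse 5, 1847 without that of KI mouse 6, and 1228 or 1615 without both tissues of mouse 5 or 6. NF-kB targets that fell numbered 6 without mouse 5 and 5 without mouse 6. Fosl2 (-4.38 to -4.04) and Irs2 (-4.01 to -3.81) lost their calls without any 1 of the 4 libraries. Bcl2a1a (-1.46 to -0.95) lost it without Tg mouse 3 or either KI mouse, Iglc1 (4.79 to 6.43) without either Tg mouse or KI mouse 6, and Apol8 (-3.63) without both tissues of mouse 6.

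In spleen the same comparison set 2 KI libraries against 1 Tg library. Col27a1 rose by 3.77 ± 0.38, St6galnac2 by 3.58 ± 0.36, Reln by 3.51 ± 0.37 and Sdc1 by 2.77 ± 0.22, while Atf3 at -6.21 ± 0.62, Gla at -4.14 ± 0.31 and Rgs1 at -4.13 ± 0.25 fell. Plasma cell genes rose in 10 of 20 with 0 that fell (13 and 2 adjusted over the list alone), with Jchain at 2.57 ± 0.32. The plasma cell list had camera adjusted p = 9.3e-07, and adjusted p = 0.233 with an estimated correlation. Marginal zone and B1 genes fell in 8 of 12 with 0 that rose (9 and 0 adjusted over the list alone), with Myof at -1.97 ± 0.21 and Cr2 at -1.58 ± 0.20. Camera gave marginal zone and B1 genes adjusted p = 1.67e-07, and adjusted p = 0.0892 with an estimated correlation. Pan T cell genes fell in 14 of 20 with 0 that rose (17 and 0 adjusted over the list alone), including Trac at -1.29 ± 0.16. The pan T cell list had camera adjusted p = 2.4e-12, and adjusted p = 0.185 with an estimated correlation. Of the 15 immediate early genes 6 fell and 0 rose (9 and 0 adjusted over the list alone). Camera gave immediate early genes adjusted p = 3.56e-08, and adjusted p = 0.25 with an estimated correlation. In the neutrophil list 1 of 16 fell, at a median of -3.71 (camera adjusted p = 2.86e-05, and 0.5 with an estimated correlation). Of the 18 germinal centre genes limma called 0, also when adjusted over the list alone (list median 0.37, camera adjusted p = 0.318, and 0.0308 without mouse 6). Bcl2 was -0.73 ± 0.24 (limma adjusted p = 0.0956), and was called from the spleen libraries alone (adjusted p = 0.0097). Limma called 839 genes, 365 higher and 474 lower, but 776 and 438 with immunoglobulin and haemoglobin genes left out and 654 and 528 after quantile normalisation; 1433 were called from spleen libraries alone, 278 without the spleen of KI mouse 5, 258 without that of mouse 6, and 382 or 293 without both tissues of mouse 5 or 6. Without mouse 5 or 6, in that order, plasma cell genes rose in 5 and 7 cases, and there fell 5 and 5 marginal zone and B1 genes, 8 and 12 pan T cell genes and 4 and 3 immediate early genes. Nr4a2 (-4.62 to -4.12), Vcam1 (1.15 to 1.21), Axl (0.97 to 1.13) and Siglec1 (1.48 to 1.78) lost their calls without either KI library, Thbd (2.18) without mouse 5, and Retnlg (-5.28 to -3.48) without either mouse.

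Whether BCL2 at the kappa locus acted differently in LN and spleen was tested as an interaction. Sema7a rose more in LN (2.96) than in spleen (0.54), a difference of 2.41 ± 0.21 (limma adjusted p = 0.00157), and Neil1 likewise (2.30 and 0.46; 1.84 ± 0.22). Plasma cell genes were higher in KI by more in LN than in spleen: Mzb1 by 1.66 ± 0.20, Sdc1 by 1.64 ± 0.26, Derl3 by 1.75 ± 0.29 and Jchain by 2.43 ± 0.37, with 6 of 20 members called and 0 the other way (14 and 0 adjusted over the list alone). The plasma cell list had camera adjusted p = 5.77e-15, and adjusted p = 0.139 with an estimated correlation. Macrophage genes went apart between tissues, with C1qc at -1.76 in LN and 0.52 in spleen (difference -2.28 ± 0.32) and Slc40a1 at -2.91 and 0.20 (difference -3.11 ± 0.42); 6 of 17 members were called lower and 0 higher (10 and 0 adjusted over the list alone). Camera gave macrophage genes adjusted p = 1.92e-10, and adjusted p = 0.139 with an estimated correlation. For interferon genes 3 of 18 were called higher, with Irf7 at 2.59 in LN and 0.40 in spleen (difference 2.19 ± 0.36), and 0 lower (15 and 0 adjusted over the list alone). The interferon list had camera adjusted p = 9.32e-14, and adjusted p = 0.206 with an estimated correlation. Proliferation genes had a median difference of 1.72 with 0 of 27 called over all genes (22 and 0 adjusted over the list alone). Camera gave proliferation genes adjusted p = 8.57e-19, and adjusted p = 0.206 with an estimated correlation. For neutrophil genes the difference had a median of 2.55 with 0 of 16 called (camera adjusted p = 0.00268, and 0.595 with an estimated correlation), a list call lost without mouse 5 (adjusted p = 0.113). The pan T cell list did not differ between tissues by camera (median -0.04, adjusted p = 0.791, and 0.0226 without mouse 6), and Bcl2 differed by 0.18 ± 0.28 (limma adjusted p = 0.843). Limma called 104 genes, 83 positive and 21 negative. In 53 the 2 tissues had opposite signs, and 9 were called in both tissues with opposite signs. This fit and the omissions below held no mouse term, though both tissues came from the same mice. All 104 genes were also called with the mouse as a fixed term. With the mouse as a fixed term 596 genes were called; the count fell to 37, 52, 7, 40, 4 and 44 without the spleen of Wt mouse 1, the LN of Wt mouse 1, the spleen of Wt mouse 2, the LN of KI mouse 5, the spleen of KI mouse 6 and the LN of KI mouse 6, and to 3, 31 and 15 without mouse 1, 5 or 6. Without mouse 1, 5 or 6, in that order, called members numbered 0, 3 and 0 of plasma cell genes, 0, 1 and 0 of macrophage genes, 1, 0 and 0 of interferon genes and 0, 1 and 0 of proliferation genes, while camera kept the calls of these lists at adjusted p up to 8.26e-08. Of 17 named called genes only Sema7a kept its call in every such omission, the others reaching adjusted p between 0.0503 and 0.236.

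**Figure D4:**
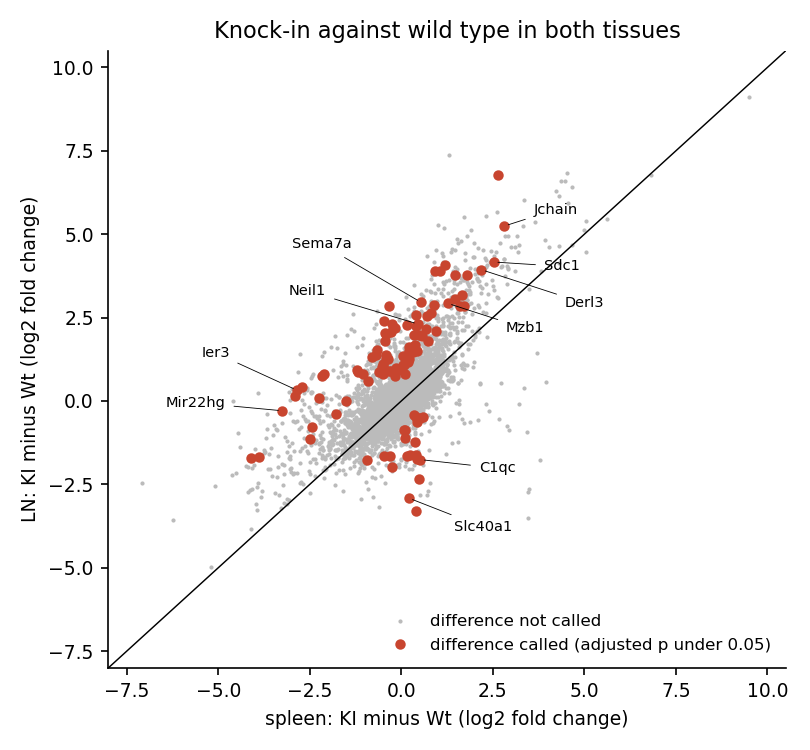
Log2 fold change of KI minus Wt in LN (vertical axis) against spleen (horizontal axis), 1 point per gene; large red points are genes called in the interaction, and the diagonal marks equal change. Sema7a lies at 2.96 in LN and 0.54 in spleen, and Slc40a1 at -2.91 and 0.20.

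For the Tg effect in LN and spleen, limma called 0 genes, with 200 at an unadjusted p under 0.05 against 544 by chance; no count-based tool was run on this contrast. The smallest p belonged to Mrc1 (the mannose receptor of macrophages) at 1.44 ± 0.32, Siglec1 at 1.99 ± 0.47, Prg2 at -2.14 ± 0.52, Sdc3 at 0.81 ± 0.21 and Axl at 1.12 ± 0.29. This contrast used the same pooled error and the lone Tg spleen library. The absence of calls does not show that the Tg effect was alike in both tissues. Macrophage genes had a median difference of 0.78 with 0 of 17 called (2 and 0 adjusted over the list alone). The macrophage list had camera adjusted p = 1.93e-07, and adjusted p = 0.476 with an estimated correlation. Neutrophil genes had a median difference of -2.58 (camera adjusted p = 2.05e-06, and 0.542 with an estimated correlation). With the mouse as a fixed term 5 genes were called, and 3 or 1 were called without the LN of Wt mouse 2 or of Tg mouse 4.

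Cell type markers differed between LN and spleen, with 1 tissue effect fitted for all genotypes. For macrophage genes called in the KI interaction, such as Slc40a1, that effect does not describe each genotype. Of the 20 pan T cell genes 19 were higher in LN and 0 lower (20 and 0 adjusted over the list alone), with Cd6 at 0.98 ± 0.06, Tcf7 at 0.96 ± 0.07 and Cd3e at 0.92 ± 0.07 (6 LN and 5 spleen libraries). Camera gave pan T cell genes adjusted p = 2.94e-24, and adjusted p = 0.0689 with an estimated correlation. Pan B cell genes were lower in LN in 18 of 20 cases and higher in 0 (18 and 0 adjusted over the list alone), with Blk at -0.76 ± 0.08. The pan B cell list had camera adjusted p = 4e-14, and adjusted p = 0.169 with an estimated correlation. Macrophage genes were lower in 15 of 17 and higher in 1 (15 and 2 adjusted over the list alone), with Hmox1 (haem oxygenase) at -4.04 ± 0.22 and Slc40a1 at -5.47 ± 0.68, against Siglec1 at 1.60 ± 0.36. Camera gave macrophage genes adjusted p = 3e-13, and adjusted p = 0.169 with an estimated correlation. Neutrophil genes were lower in 15 of 16 and higher in 0 (16 and 0 adjusted over the list alone), with Csf3r at -4.86 ± 0.47 and Cxcr2 at -4.55 ± 0.53. The neutrophil list had camera adjusted p = 3.18e-12, and adjusted p = 0.309 with an estimated correlation. Megakaryocyte and platelet genes were lower in 4 of 5 and higher in 0 (4 and 1 adjusted over the list alone), with Ppbp at -7.08 ± 0.64 and Pf4 at -5.72 ± 0.83. Camera gave megakaryocyte genes adjusted p = 0.00029, and adjusted p = 0.169 with an estimated correlation. Erythroid genes were lower in 5 of 16 (8 adjusted over the list alone), with Klf1 at -3.32 ± 0.55. The erythroid list had camera adjusted p = 3.57e-05, and adjusted p = 0.361 with an estimated correlation. Marginal zone and B1 genes were lower in 7 of 12 and higher in 1 (8 and 2 adjusted over the list alone), with S1pr3 (a receptor that positions marginal zone B cells) at -2.06 ± 0.26, against Cd5 at 0.85 ± 0.07. Camera gave marginal zone and B1 genes adjusted p = 0.000411, and adjusted p = 0.169 with an estimated correlation. The chemokine Ccl22 was higher in LN by 3.49 ± 0.50, Fscn1 (a marker of mature dendritic cells) by 2.35 ± 0.41 and Itgae by 1.84 ± 0.13. Bcl2 was 0.14 ± 0.12 (limma adjusted p = 0.519).

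Limma called 1645 genes between tissues, 658 higher and 987 lower in LN, 494 over 2-fold, or 837 and 857 after quantile normalisation. Of these genes, 857 were also called in Wt mice alone and 703 in KI mice alone, with fewer libraries fitted. In 635 of them the LN and spleen libraries did not overlap. Without mouse 1, 1084 genes were called. The neutrophil genes S100a8 (-5.97 to -4.56) and S100a9 (-5.88 to -4.23) lost their calls without 1 library in 9 and 8 of the 11 cases, and Apol7c (1.67 to 2.09) in 7. Camp (-3.83) lost it without the Tg spleen, and Fscn1 (2.21) and Siglec1 (1.55) without mouse 1.

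In KI mice 516 genes were called higher in both tissues and 601 lower in both, and 9 were called in opposite directions; both tissues came from the same mice. No gene was shared between the Tg and KI calls in LN, since limma called 0 in Tg. The 28 genes higher and 1 lower (Xist) by DESeq2 in Tg LN were all called the same way by DESeq2 in KI LN. For independent lists 3.69 and 0.11 would be shared. The simulations of unchanged groups shared 3 to 18 and 0 to 9, but left KI unchanged too. In them 10 to 36 genes were called higher in KI and 11 to 38 lower, against 1436 and 1198 observed. Their ranges therefore cannot judge the observed overlap. Both comparisons used the same 2 Wt LN libraries, from which part of the excess may come.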

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

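Of the tests below, the pair on light chains and the 2 on immediate early genes were chosen after the result was seen, and that on linked genes before.

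Results that differed between groups were those of the KI interaction, where the effect in LN was tested against that in spleen: 104 genes and 15 gene lists by camera, 0 of them with an estimated correlation. The 17 named genes past the threshold had differences (log2, LN effect minus spleen effect) of 2.41 for Sema7a, -2.82 for Apol7c, 1.84 for Neil1, 1.66 for Mzb1, 2.95 for Mir22hg, 1.64 for Sdc1, 1.75 for Derl3, 2.43 for Jchain, -3.11 for Slc40a1, -2.28 for C1qc, -2.18 for C1qa, 1.83 for Oas1a, 2.19 for Irf7, 1.30 for Zbp1, 1.28 for Hmces, 3.17 for Ier3 and 1.38 for Dnajb9. Without the spleen of KI mouse 6 only 4 genes passed, and without that of Wt mouse 2 only 7. These omissions were fitted without a mouse term. With all libraries and the mouse as a fixed term, all 104 genes were called. In no group were there 4 libraries, so single libraries were not tested as outliers.

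Igkv transcripts were nearly missing from KI mouse 6 and Igkc was lower than in every other library, with lambda at 96.5% and 98.0% of the light chain constant signal. A single lambda clone would have concentrated the heavy chain. The strongest Ighv segment held 15.1% of the Ighv signal in the spleen of mouse 6 and 9.17% in its LN. In libraries of the other mice it held between 5.26% (LN of Tg mouse 3) and 10.7% (spleen of KI mouse 5). The spleen of mouse 6 was thus the most concentrated library, though no segment held most of its signal. Insertion of BCL2 on both Igk alleles of mouse 6 and on 1 allele of mouse 5 was left open, as the alleles of the mice were not analysed here. In 1 tissue 78 of the 79 Igkv segments and in the other 79 were lower in mouse 6 than in every other library of that tissue, which restates the low kappa signal and cannot tell its cause.

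Immediate early genes fell in KI spleens. A lower share of T cells, all of them lost alike, would have lowered them by no more than T cell genes. Yet 7 of the 10 called members fell by more than the pan T cell gene that fell most (-1.67). A loss confined to some T cells was not tested. A lower share of neutrophils, whose genes had a median of -2.25 in the same comparison with 0 of 16 called, was not tested and stays open. Handling of the tissue that differed between KI and other mice cannot be told apart from genotype: 13 of 15 members lay lower in both KI spleens than in all other spleens, against 28.9% of all genes and 10% by chance, and in LN 6 of 15 did, against 25% of all genes and 6.67% by chance. RNA came from dissociated cells and the labels give no day of collection, which keeps handling open; an effect of the knock-in itself was not tested apart from it.

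Large changes shared by both tissues of KI mice were counted without immunoglobulin and T cell receptor genes and Jchain. Called and changed over 4-fold against both Wt and Tg in both tissues were 28 genes, 17 up and 11 down. Several lay close together: 4 pairs were within 10 measured genes of each other, against a median of 1 and a 95th percentile of 2 in 10000 random sets (permutation p = 0.0068). These pairs joined BC018473, St6galnac1 and St6galnac2 on chromosome 11 and Etl4 and Spag6 on chromosome 2; BC018473, St6galnac1 and Spag6 were chosen after their values were seen. Linked genes of another genetic background in the KI mice may account for these 5 genes. Closeness alone cannot tell this from co-regulation of neighbours, which was not tested. The other genes of the set are not addressed by the test.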

How the results depend on the processing

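Chosen after seeing the data were the count-based tools, treat, the omission of mice, total-count and quantile scaling, the minimum value of 100, and fry with a mouse block. Where a count fell on leaving out samples, fewer samples were fitted; the cause of the other changes was not tested. Over 231 values of single named genes other than Bcl2 and 4709 alternatives, 4265 kept direction and call, 433 lost the call, 11 gained it and 0 reversed. Total-count scaling, quantile normalisation, pseudocounts of 0.1 and 5, the minimum value of 100 (172 genes removed) and the mouse as a random term kept every count of called genes within 1.5 times. The stricter CPM filter removed 0 genes and so tested nothing. The random term, at a consensus correlation of 0.0168, could change little.

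The treat test against 1.5-fold called 525 (LN KI against Wt), 457 (LN KI against Tg), 159 (spleen KI against Wt), 46 (spleen KI against Tg), 2 (KI interaction) and 278 (tissue). Without mouse 1 the counts were 1695 (LN KI against Wt), 677 (spleen KI against Wt), 3 (KI interaction) and 1084 (tissue); without mouse 5 they were 1318, 1228 (LN KI against Tg), 645, 382 (spleen KI against Tg) and 31, and without mouse 6 1772, 1615, 626, 293 and 15. LN KI against Tg gave 1830 from the 2 groups alone, spleen KI against Tg 1433 from spleen alone, and the mouse as a fixed term gave 596 for the KI and 5 for the Tg interaction. DESeq2 called 29 genes in LN Tg against Wt. Leaving out single libraries gave 0 to 13 (LN Tg against Wt), 1465 to 1959 (LN KI against Wt), 1341 to 2527 (LN KI against Tg), 624 to 747 (spleen KI against Wt), 0 to 0 (spleen Tg against Wt), 258 to 278 (spleen KI against Tg), 4 to 118 (KI interaction), 0 to 3 (Tg interaction) and 1221 to 1742 (tissue).

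Bcl2 in LN KI against Wt was no longer called by treat or from LN alone (-0.81), edgeR (-0.79, -0.78 and -0.79), limma-voom (-0.80), or without mouse 1 (-0.92) or 5 (-0.60); single omissions gave -1.02 to -0.60. Against Tg it lost the call by treat and from 2 groups (-0.83), by limma-voom (-0.83) and without mouse 5 (-0.62), with single omissions at -1.14 to -0.52. In spleen against Wt it lost it by treat (-0.98) and without mouse 1 (-0.93) or 5 (-0.95), with omissions at -1.04 to -0.93; against Tg it was gained from spleen alone (-0.73), with omissions at -0.76 to -0.70. In LN Tg against Wt omissions gave -0.29 (reversed, without Tg mouse 4) to 0.33, in spleen -0.31 to -0.20, in the KI interaction -0.03 to 0.38, in the Tg interaction -0.03 to 0.59, and between tissues 0.07 to 0.19.

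Gene lists called by camera numbered 16, 11, 13, 16, 7, 17, 15, 9 and 19 in LN Tg against Wt, LN KI against Wt, LN KI against Tg, spleen KI against Wt, spleen Tg against Wt, spleen KI against Tg, the KI and Tg interactions and tissue; camera with an estimated correlation called 0 in each. Fry, with or without a mouse block, called 0 in the Tg comparisons with Wt and the Tg interaction, 12 in each LN KI comparison, 6 in spleen KI against Wt, 7 in spleen KI against Tg and 8 in the KI interaction; for tissue it called 13, without a block. Depth limits the lowest genes: values under the minimum of the table were not analysed here.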

Other observations

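The tests on shared controls and on splits by tissue were chosen before the result was seen, and that on all splits parting the mouse pairs was chosen after it.

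The pro-apoptotic Bmf rose in both tissues of KI mice (limma adjusted p = 0.000891 in LN and 0.00193 in spleen, n = 2 against 2), by 1.97 ± 0.25 on the log2 scale in LN, and Bcl2l11 (Bim) rose in LN by 0.98 ± 0.16, while Pmaip1 (Noxa) in spleen was -2.41 ± 0.33. Neither family list was called by camera in KI LN: of 9 pro-apoptotic genes 3 rose and 1 fell, and of 7 anti-apoptotic genes 1 rose and 1 fell. In Tg LN both were called by camera (anti-apoptotic adjusted p = 0.0233 and pro-apoptotic 0.00784, both 0.275 with an estimated correlation), with 0 members called. Regulatory T cell genes fell in KI spleen in 5 of 10 cases with 0 that rose (5 and 0 adjusted over the list alone). Camera gave regulatory T cell genes adjusted p = 0.0016, and adjusted p = 0.55 with an estimated correlation. Without mouse 1, 5 or 6, in that order, 3, 3 and 0 of them fell, with a median of -0.43 and camera adjusted p = 0.0297 without mouse 6. Of 15 NK and cytotoxic genes in spleen 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Ifng at -2.45 ± 0.39 and Nkg7 at -1.03 ± 0.19. The NK cell list had camera adjusted p = 0.00335, and adjusted p = 0.55 with an estimated correlation. Without mouse 1, 5 or 6 NK cell genes that fell numbered 3, 2 and 3, and 0 rose. The call of Nkg7 was lost without Wt mouse 2 or KI mouse 5 (-0.89 to -0.86). Proliferation genes in KI spleen had a median of -0.57, with 0 of 27 that rose and 1 that fell (0 and 1 adjusted over the list alone). Their list had camera adjusted p = 0.000274, and adjusted p = 0.55 with an estimated correlation. That median was -0.18 without mouse 6 (camera adjusted p = 0.0395), -0.79 without mouse 5 and -0.87 without mouse 1. Of 20 genes mutated in follicular lymphoma 4 rose and 4 fell in KI LN, including Myc at -1.42 ± 0.15.

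Rag1, which starts V(D)J recombination, was chosen after its values were seen. Its normalised signal in KI mice was 92.6 and 45.0 in spleen and LN of mouse 5 and 360 and 54.0 in those of mouse 6, against 4.64 and 21.2 in the Wt spleens and 0 and 3.28 in Wt LN.

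Log2 fold changes of Tg and KI against Wt in LN went together, and the shared Wt libraries may account for part of their covariance. Their covariance over genes was 0.0665, within the range of 0.0620 to 0.163 from 100 simulations of unchanged groups against shared controls. Their correlation, 0.252, and the share of genes with the same sign, 57.0%, lay below the simulated 0.322 to 0.621 and 65.6% to 67.9%. Genes higher in both at an unadjusted p under 0.05 numbered 178, against a range of 55 to 95 in those simulations, and those lower in both 75, against 51 to 98. The 2 control libraries were not split, as each part would hold 1, so part of the excess may come from the shared controls. These simulations left both groups unchanged, while in KI 2053 genes were higher and 2062 lower at an unadjusted p under 0.05. They also gave Wt a spread pooled over all groups. The SD of the log2 difference between replicates was 0.493 in LN Wt and 0.918 in LN KI. The simulated ranges therefore cannot set the share due to the controls.

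Among 100 of the 462 splits of the 11 libraries into groups of 6 and 5, 1 (that by tissue) called as many genes as the 1645 found between LN and spleen, and the highest other split called 1008. That other split exchanged the tissue labels of all 5 mouse pairs, and so is the tissue split mirrored except for the LN of mouse 3. Of all 32 splits that part the 5 mouse pairs, with the LN of mouse 3 in the larger group, 1 called as many, and the highest besides these 2 called 14.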
